A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

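Poly(A) sites were measured by 3' READS, an RNA sequencing method that captures the ends of polyadenylated RNA so that each read marks the place where a transcript was cleaved and polyadenylated. The samples were 2 libraries, replicates A and B, of wild-type fission yeast (Schizosaccharomyces pombe) in exponential growth in YPD, a rich medium, at 30 °C. They form 1 group, so no condition was compared with another; the comparisons are between genes. The labels do not say whether the replicates came from separate cultures, and the difference between them may therefore be technical.

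Per the submitters' processing notes, Bowtie was used; its version, its settings, the handling of reads with several matches and the genome build are not given in the sources used here. Reads of near-identical gene copies, such as paralogous ribosomal protein genes, may have been split or lost in that step. Per the file headers, the authors deposited 1 table per replicate and 1 merged table, each with 5289 features. For every feature the tables give read signal values (the reads at the most used position, the total over positions 1 to 400 after the stop codon, and the sum over the open reading frame, ORF) and the level at each position as a share of the highest position. The deposited signal values were not whole numbers. Low values were multiples of a single step per table, 0.930 in replicate A and 0.869 in replicate B: 100% of the 1957 and 2079 values of at most 100 reads came out whole within a tolerance of 0.1. Larger values were not checked in this way. All signal values were divided by the step to give reads. Features without reads had no profile.

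The stop codon coordinates of all 5113 protein-coding features were equal to those of the RefSeq annotation of assembly ASM294v3, and 5112 of them ended in a stop codon there. Names of neighbouring genes, annotated 3' ends and sequence were taken from that assembly, with positions counted from 1 at the first base after the stop codon. The other features were 124 tRNA genes, 32 pseudogenes and 20 features without a match; they entered no comparison.

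The reads in the window numbered 50972138 in replicate A and 54744262 in replicate B. A gene was measured if it had at least 50 reads in each replicate, which 3818 genes did. Reads of 1 library are not independent molecules, so errors from counting are lower limits. For each gene and replicate the mean position (weighted by reads), the width (distance from the 10th to the 90th percentile of the reads) and the effective number of sites (the exponential of the Shannon entropy of the profile) were computed, and the value of a gene is the mean of its 2 replicates. The mean positions differed from the weighted average location in the deposited tables by at most 0.0487 nt in replicate A and 0.0950 nt in replicate B.

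A set of 27 gene lists was fixed from gene symbols and annotated product names before the data were examined. Each list's median position and median width were compared with 100000 random lists of measured genes of the same size (two-sided permutation test), and the mean pairwise overlap of its profiles in bins of 20 nt with 10000 random lists (one-sided permutation test for higher overlap). P-values were adjusted by Benjamini and Hochberg over the 27 lists of each test. The smallest p these permutations can give are 2e-05 and 1e-04. Genes are not independent replicates, and the p-values speak of these libraries only. Search patterns caught some genes outside the theme of a list: 12 of 20 measured members of the histone list bind or modify histones, 9 members of the protein kinase list are regulators or binding partners of kinases, and 6 members of the ribosome biogenesis list, 3 of the aminoacyl-tRNA ligase list and 2 of the spliceosome list have other functions. Lists were tested as fixed.

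Genes were also grouped by whether the next protein-coding gene downstream lies on the same strand (tandem) or the opposite strand (convergent), and positions were correlated across genes with the distance to that gene, with two-sided tests of 100000 permutations and adjustment over the 6 correlations. The distance runs from the stop codon to the near end of the neighbour's coding sequence. That end is the start codon of a tandem neighbour and the stop codon of a convergent one. The share of genes with AATAAA or one of its 18 single-base variants 10 to 40 nt upstream of the most used position was compared with 100 random draws of a site from positions 50 to 400 of the same genes. Pairs of duplicated ribosomal protein genes were compared with random pairings of the same genes.

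Apart from tef3 and some genes of the closing sections, genes named in the text were chosen by a rule fixed together with the lists. Among genes whose replicate mean positions differed by at most 10 nt, these are the 6 with the smallest and the 6 with the largest position, the 5 narrowest and 5 widest, and the 4 convergent and 4 tandem genes with the largest position. From each list past the threshold (adjusted p under 0.05) they are the extreme members, with the 2 nearest the median for position. The 5 genes with the largest replicate difference, the 3 closest and 3 farthest ribosomal protein pairs and 12 reference genes complete the rule. Ties were broken by identifier, which decided the narrowest genes, since 128 genes tied at a width of 0 nt in both replicates. Of the reference genes, nmt1 and cdc25 were not measured. For 2 genes, 1 of them with a large replicate difference and 1 with reads inside the ORF, the values are not reported here.

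The tests were checked on simulated libraries drawn from the merged profiles of the 3818 genes at their real depth. Counting alone gave a median error of 0.524 nt in mean position. A shift of 40 nt was called in 34.0% of lists of 15 genes, 79.5% of lists of 70 genes and 96.0% of lists of 140 genes at an unadjusted p under 0.05, and lists without a shift in 4.0%, 6.0% and 5.0%. The orientation test called 9.0% of 100 random groupings without a shift and 100% with 20 nt. For width, 88.5% of lists of 70 genes shifted by 40 nt were called.

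Alternatives covered each replicate alone, the merged table, median and most used positions in place of the mean, other read filters, a window of 300 nt, removal of sites under 5% of the highest, random lists matched on read depth, other measures of width, other bins, and other definitions of the next gene. The lists matched on read depth were drawn within 10 groups of depth from all measured genes, members of the tested list included. A few alternatives on annotated 3' ends, list members, reads past the next ORF and distance to the next gene were chosen after seeing the data. Shares of reads carry 95% Wilson intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.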

Results

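The data are maps of poly(A) sites in the first 400 nt after the stop codon of fission yeast genes, from 2 libraries of wild-type cells in exponential growth in rich medium at 30 °C. The series title links the location of these sites to the function of genes, and the comparisons follow that question. Replicate A held 50972138 reads in the windows and replicate B 54744262. The translation elongation factor gene tef3 alone took 6.74% of the reads in replicate A (95% Wilson interval 6.73% to 6.74%) and 9.38% in replicate B (9.38% to 9.39%), and the 5 leading features took 23.36% (23.35% to 23.37%) and 26.35% (26.34% to 26.36%). Of 5113 protein-coding genes, 3818 had at least 50 reads in each replicate, with a median of 655 reads in A and 548.5 in B. Among the measured genes, 23.2% have an annotated 3' end more than 400 nt after the stop codon, against 45.4% of the 1295 others, so long 3' untranslated regions (UTRs) are seen only in part.

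The first comparison asked how closely replicates A and B match. The abundant glycolytic gene tdh1 (SPBC32F12.11; chromosome II of assembly ASM294v3, most used site at 2808994) ended at a mean position of 347 ± 0.509 nt (SD, n = 2), and the phosphatase gene pho1 at 132 ± 0.000361 nt (SD, n = 2). Genes with few reads were less certain. The mating regulator ste11, with 68 reads in A and 110 in B, had mean positions of 272 and 222 nt, and cdc2, which encodes the main cyclin-dependent kinase, had 337 and 273 nt. Over all genes the median absolute difference between replicates was 5.18 nt, and 66.1% of genes differed by at most 10 nt. Genes with under 500 reads in the shallower replicate differed by a median of 10.3 nt and those with at least 5000 by 0.692 nt. Simulated draws of independent reads at the same depths gave a median of 1.09 nt, a lower limit for counting error. The read totals per gene also differed by more than sampling noise (chi-square over degrees of freedom 404), and A and B were kept as separate libraries. Across genes, Pearson's r of the mean positions was 0.973. The 2 profiles of a gene overlapped by a median of 85.9%, against 3.78% for profiles of different genes paired at random. Among the largest differences were those of irs4 (325 nt in A, 144 nt in B), acr1 (317 and 138 nt), SPAC652.01 (157 and 330 nt) and SPCC1672.09 (108 and 267 nt), all with at most 180 reads per replicate.

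**Figure D1:**
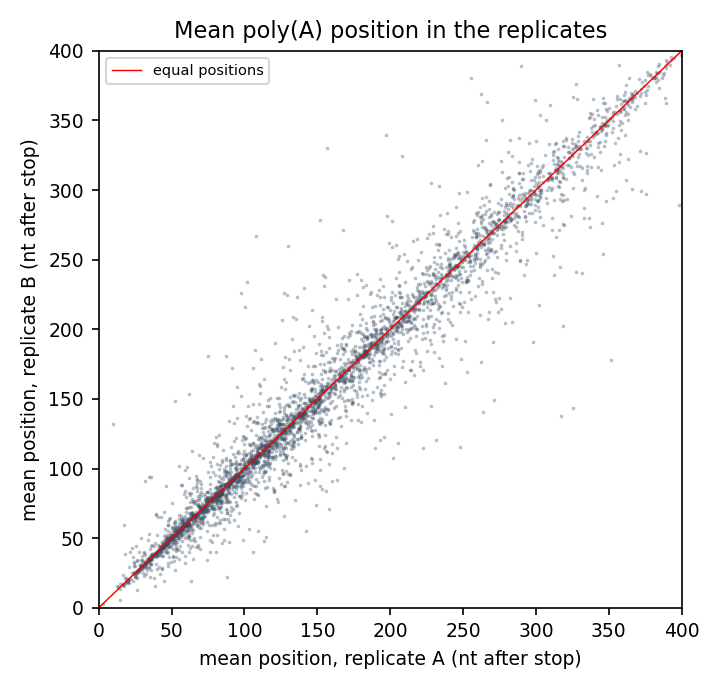
Each point is a measured gene, with its mean poly(A) position in nt after the stop codon in replicate A (x axis) and replicate B (y axis); the line marks equal positions. The 3818 genes follow the line with Pearson's r of 0.973 across genes, and a minority lie far from it.

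Across the genome, poly(A) sites lay from directly after the stop codon to the end of the window. The shortest mean positions that held in both replicates were those of csn4, a COP9 signalosome subunit (SPAC22A12.03c; 3.01 ± 0.00983 nt, SD, n = 2; most used site at 1160216 on chromosome I), and set11, a methyltransferase of ribosomal proteins (10.3 ± 6.09 nt), for which most of the ORF and window reads lay inside the ORF. The mevalonate kinase gene erg12 (14.1 ± 2.36 nt), ure6 (14.3 ± 0.985 nt), cmc1 (14.4 ± 0.751 nt) and lip2 (15.8 ± 1.62 nt) followed. The largest were those of the mitochondrial import gene tim50 (398 ± 2.07 nt), phx1 (395 ± 0.193 nt), the GTPase gene rho3 (394 ± 2.31 nt), the Polo kinase gene plo1 (393 ± 0.229 nt), fhn1 (391 ± 2.76 nt) and mcp4 (391 ± 1.59 nt). These 6 values lie against the edge of the window, and 5 of these genes have no annotated end inside it: those of tim50, phx1, rho3, plo1 and fhn1 lie 630, 926, 533, 474 and 1902 nt after the stop codon. The median position of all genes was 143 nt, with 25th and 75th percentiles of 86.5 and 224 nt. The most used position took a median of 43.0% of a gene's reads, and the effective number of sites had a median of 4.73. The width had a median of 62.5 nt. It was 0 nt in both replicates for 131 genes, such as urg3, urg1, sst6, coa2 and rpc19. The widest profiles were those of fma2 (372 ± 4.24 nt, SD, n = 2), sil1 (360.5 ± 4.95 nt), mim2 (346.5 ± 16.3 nt), shf1 (340.5 ± 16.3 nt) and noc12 (337 nt in both replicates). Over the 3694 measured genes with an annotated 3' UTR, the most used site lay a median of 65 nt upstream of the annotated 3' end. This median includes genes whose annotated end lies past the window (23.2% of all measured genes). For those genes a site inside the window can only lie upstream of that end. The median is therefore set in part by the window and is not a measure of error in the annotation.

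Among reference genes, leu1, an enzyme of leucine synthesis, ended at 43.8 ± 0.379 nt (SD, n = 2), ura4, an enzyme of uracil synthesis, at 103 ± 3.18 nt, and the histone H3 gene hht2 at 148 ± 0.333 nt. Within the window the actin gene act1 had a mean position of 94.5 ± 10.1 nt, with a width of 32 nt in replicate A and 276 nt in replicate B. The annotated end of act1 lies 664 nt after the stop codon, past the window. The phosphate-regulated gene tgp1 had a mean position of 349 ± 5.80 nt and an annotated end at 473 nt, also past the window. The alcohol dehydrogenase gene adh1 had 111 reads in A and 121 in B within the window, a position of 276 ± 51.8 nt and an annotated end 478 nt after the stop codon.

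The central comparison asked whether genes of a shared function end at similar distances. Genes of cytosolic ribosomal proteins ended close to the stop codon: their median position was 54.8 nt, against 148 nt for the other genes, and 132 of the 139 lay below the median of all genes. Spliceosome genes also lay closer, at 106 nt, with 58 of 90 below that median. Protein kinase genes lay farther, at 202 nt, with 53 of 73 above it, and genes of septation and the M/G1 transition at 286 nt, with 8 of 11 above; 2 of these 11 genes are also in the kinase list. Of the 27 lists, these 4 passed the threshold, 2 lower and 2 higher. Only 11 of the 21 septation genes were measured, 73 of the 105 kinase genes and 90 of the 113 spliceosome genes, against all 139 ribosomal protein genes. Annotated ends past the window belong to 47.6%, 32.4%, 25.7% and 1.44% of these full lists, and to 28.8% of all protein-coding genes. The list positions therefore describe measured genes within the window only. Ribosomal protein genes ranged from rps1602 (26.2 ± 0.132 nt, SD, n = 2) to rpl3402 (224 ± 0.593 nt), with rpp0 (54.8 ± 0.516 nt) and rpl13 (54.8 ± 0.890 nt) nearest the list median. Spliceosome genes ran from cwf28 (31.7 ± 4.06 nt) to lsm5 (325 ± 3.57 nt), with the helicase gene prp16 (106 ± 1.63 nt) and xap5 (105 ± 0.0983 nt) in the middle. Kinase genes ran from ppk27 (46.7 ± 6.11 nt) to hal4 (383 ± 4.37 nt), with the stress kinase gene wis4 (204 ± 0.481 nt) and sin1 (180 ± 0.960 nt), whose product binds a MAP kinase, in the middle. In the septation list klp8, a kinesin-like gene, had the lowest position (33.8 ± 3.05 nt) and plo1 the highest (393 ± 0.229 nt), with the kinase genes sid2 (319 ± 5.44 nt) and fin1 (334 ± 6.97 nt) nearest the median among members with close replicates.

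By the two-sided permutation test, adjusted over the 27 lists, p was 0.00054 for the ribosomal protein genes (unadjusted 2e-05, the smallest possible), 0.0090 for the spliceosome, 0.0090 for the protein kinases and 0.00931 for septation and M/G1 genes. The difference for the ribosomal protein genes was -92.9 nt, and with the next gene over 400 nt away -136.1 nt (adjusted permutation p = 0.00038). Against random lists matched on read depth the difference was -44.0 nt (adjusted permutation p = 0.00054). Those lists could hold ribosomal protein genes too, so the last value is not a difference from other genes alone. The medians in replicates A and B were 54.4 and 55.0 nt for ribosomal proteins, 107 and 106 nt for the spliceosome, 204 and 203 nt for kinases, and 315 and 240 nt for septation genes; in replicate B alone the septation list lost its call (difference 97.7 nt, adjusted permutation p = 0.125), as it did with median positions (130.5 nt, 0.0556), with positions 1 to 300 (53.1 nt, 0.373) and with means over members (69.7 nt, 0.0579). The spliceosome, which lay -38.8 nt from other genes, lost its call with median positions (-37.75 nt, permutation p = 0.0556), at 200 reads (-31.7 nt, 0.0883), with annotated ends within 400 nt (-27.7 nt, 0.138) and with the next gene of any kind over 400 nt away (-11.9 nt, 0.851), where the kinases lost theirs too (31.8 nt, 0.542) and the septation list was too small to test. Only 19 of the 27 lists kept enough genes for that last setting, so the calls lost there may reflect smaller lists. The differences shrank there too, from -38.8 to -11.9 nt for the spliceosome and from 60.3 to 31.8 nt for the kinases. That of the ribosomal protein genes went from -92.9 to -136.1 nt. Whether the room downstream accounts for the lost calls was not tested.

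Mitochondrial ribosomal protein genes, at 151 nt, had 32 of 66 members below the median of all genes and did not pass (adjusted permutation p = 0.813). Set against them directly, a test chosen after seeing the values, cytosolic ribosomal protein genes had a position that was lower (difference -96.1 nt; permutation p = 2.5e-05 adjusted over 5 such tests). Ergosterol synthesis (213 nt), meiosis (189 nt) and aminoacyl-tRNA ligase genes (100.52 nt) had unadjusted permutation p of 0.0227, 0.0231 and 0.0470 and adjusted p of 0.104, 0.104 and 0.160. Lists with median positions that did not pass also included ribosome biogenesis (127 nt), translation factors (140 nt), chaperones (132 nt), nuclear pore (118 nt), vacuolar ATPase (135 nt), the cleavage and polyadenylation machinery (140.2 nt) and the secretory pathway (143 nt). Farther from the stop codon, again without passing, were the proteasome (173 nt), the histone list (181 nt), glycolysis and fermentation (163 nt), oxidative phosphorylation (183 nt), the tricarboxylic acid cycle (184 nt), RNA polymerase II (218 nt), G1/S transcripts (168 nt), transcription factors (198 nt), core stress response (206 nt), membrane transporters (186 nt), cell wall (168 nt) and ubiquitin conjugation (146 nt). Some of these lists passed under an alternative: the histone list at 200 reads (142.8 nt above other genes, adjusted permutation p = 0.00108, against 37.3 nt in the main comparison), meiosis without a read filter (43.8 nt, 0.0153), and with means over members the ligases (-49.6 nt), core stress response (56.6 nt) and membrane transporters (39.2 nt; 0.0274 for each).

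**Figure D2:**
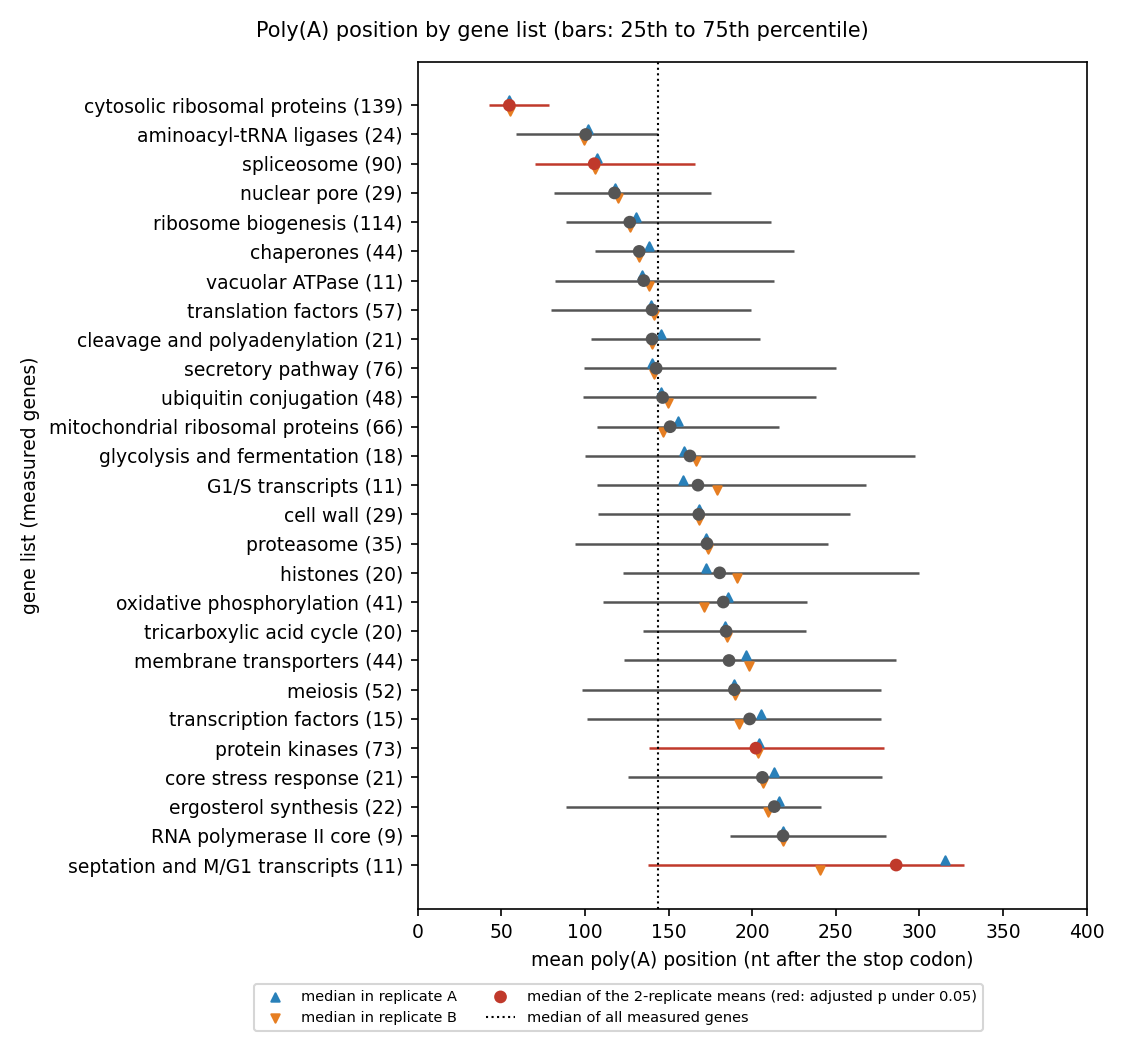
Median mean poly(A) position (x axis, nt after the stop codon) of the 27 gene lists (y axis, measured genes in parentheses), with the 25th to 75th percentile of genes as bars and each replicate's median as a triangle. The 4 lists in red passed the threshold, from cytosolic ribosomal proteins at 54.8 nt to septation and M/G1 transcripts at 286 nt, whose replicate medians lie apart.

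**Figure D3:**
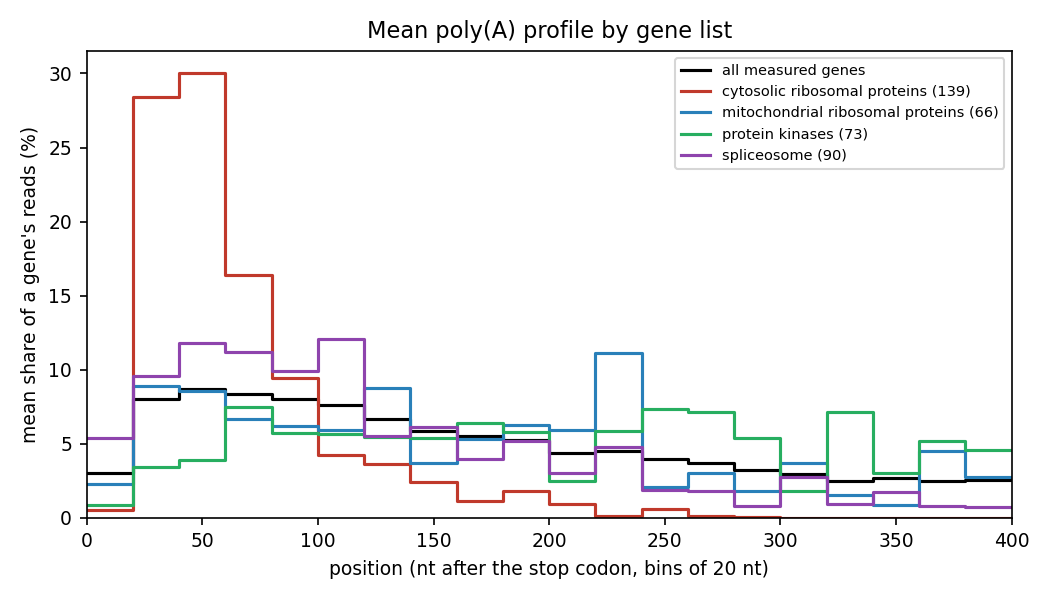
Mean share of a gene's reads (y axis, %) by position after the stop codon (x axis, bins of 20 nt) for all measured genes and 4 gene lists. Reads of cytosolic ribosomal protein genes concentrate before 100 nt, where their median position of 54.8 nt lies, and those of protein kinase genes extend through the window.

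Profiles of ribosomal protein genes were also narrow. Their median width was 9 nt, against 65 nt for the other genes, with 118 of 139 below the median of all genes. Ribosome biogenesis genes had a median width of 28.5 nt, with 78 of 114 below. Within the ribosomal protein list rpl301 had a width of 0 nt in both replicates, with 94.8% of its reads at 1 position, and rpl1101 had the widest profile at 178 nt in both. Among ribosome biogenesis genes, imp3 of the U3 particle had a width of 0 nt and rcl1 of 335.5 ± 26.2 nt (SD, n = 2). The adjusted two-sided permutation p were 0.00054 (unadjusted 2e-05, the smallest possible) and 0.00081, and none of the other 25 lists passed. Both lists are also deeply sequenced, with median read totals of 152949 and 5390 per gene. Against random lists matched on read depth neither passed: the difference was -9 nt for ribosomal proteins (adjusted permutation p = 0.110) and -17 nt for ribosome biogenesis (adjusted permutation p = 0.195). The matched lists were drawn from all measured genes, members of the tested list included. Ribosomal protein genes are among the deepest genes, so they were compared in part with themselves. For them this test cannot say whether depth accounts for the narrow profiles. Ribosome biogenesis, at -35 nt from other genes, also lost its call with the effective number of sites (-0.309, permutation p = 0.675), where the cell wall list passed (-1.54, 0.0427), and with the next gene over 400 nt away, where the difference was as large (-42.0 nt, 0.175); with the standard deviation as width the secretory pathway (16.3 nt, 0.00702) and translation factors (-11.5 nt, 0.0439) passed too.

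Members of 3 lists had profiles that overlapped more than those of random genes. Cytosolic ribosomal protein genes overlapped pairwise by a mean of 25.4%, against 11.7% for random lists, aminoacyl-tRNA ligase genes by 18.5% and spliceosome genes by 14.6%. Adjusted one-sided permutation p were 0.0027 (unadjusted 1e-04, the smallest possible), 0.0225 and 0.0121. With profiles shifted to a common mean position, only their shape counted. Shape includes width, so this overlap is not separate from the widths above. The cytosolic ribosomal protein genes kept their call. The difference for the ligases was -0.484 points and for the spliceosome 0.0967 points (adjusted permutation p = 0.982 for both), while glycolysis and fermentation (23.8 points, 0.0018) and ribosome biogenesis (8.502 points, 0.00135) passed. In the main comparison the ligases and the spliceosome lay 6.77 and 2.95 points above random lists. These 2 lists did not pass with positions 1 to 300 (5.71 and 2.09 points, permutation p = 0.0513 and 0.0720) or with annotated ends within 400 nt (4.87 and 2.42 points, 0.142 for both). The same held with the next gene over 400 nt away (4.57 and 0.962 points, 0.331 and 0.655). The ligases also did not pass in bins of 40 nt (6.66 points, 0.104), nor the spliceosome at 200 reads (1.80 points, 0.410).

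The room downstream of a gene was compared next, since genes of this compact genome lie close together. Genes followed by a tandem gene ended at a median of 163 nt (1576 genes) and genes followed by a convergent gene at 133 nt (2221 genes). The largest positions among convergent genes were those of rho3, fhn1, mcp4 and the phosphatase gene ptc3 (388 ± 4.20 nt, SD, n = 2), and among tandem genes those of tim50, phx1, plo1 and the import receptor gene tom40 (391 ± 1.24 nt). The difference was 30.6 nt (two-sided permutation p = 2e-05, the smallest possible). Tandem neighbours were also farther away, with a median distance of 702 nt against 373 nt. These distances end at a start codon for tandem and at a stop codon for convergent neighbours, so equal distances are not fully alike. Within 5 equal groups by this distance, a comparison chosen after seeing the data, the difference turned to -14.9 nt (stratified permutation p = 0.00044). In the group with the closest neighbours tandem genes ended at 68.4 nt and convergent genes at 95.8 nt (permutation p = 0.0003 adjusted over the 5 groups); in the group with the farthest they ended at 195 and 194 nt (adjusted permutation p = 0.930). With noncoding genes counted as neighbours the pooled difference was 0.737 nt (permutation p = 0.896).

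Position rose with the distance to the next coding gene. Spearman's rho across genes, which are not independent replicates, was 0.371 over all genes, 0.313 over tandem and 0.383 over convergent genes (permutation p = 2e-05 for each, the smallest possible, and 2.4e-05 adjusted over 6 correlations). Pearson's r was 0.0823 and 0.279 over all and convergent genes (the same permutation p), and 0.0431 over tandem genes (permutation p = 0.102, raw and adjusted). The next coding gene lay at a median of 598 nt for cytosolic ribosomal protein genes and 495 nt for others. The most used site lay past the stop codon of the convergent neighbour in 134 of 2221 genes (6.03%).

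**Figure D4:**
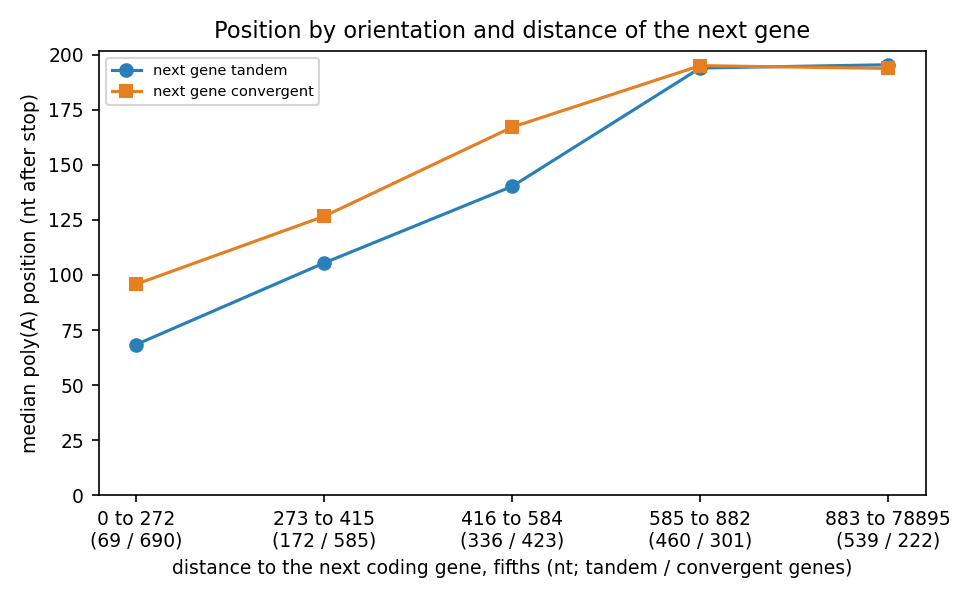
Median poly(A) position (y axis, nt after the stop codon) of genes with a tandem or a convergent next coding gene, in 5 equal groups by distance to that gene (x axis, nt, with the number of genes of each kind). Positions rise with distance up to the group of 585 to 882 nt and change little beyond it, and tandem genes lie below convergent genes in the 3 groups with the closest neighbours.

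The sequence around the most used site held the canonical signal more often than elsewhere in the same windows. AATAAA lay 10 to 40 nt upstream of the site in 20.6% of genes, against a mean of 4.99% for random positions, and AATAAA or a single-base variant in 71.3% against 36.2%. None of 100 random draws exceeded 38.7% (permutation p = 0.0099, the smallest these draws can give). AATAAA was the hexamer with the largest excess over random positions in these genes, followed by TAATAA (15.5% against 3.65%). Upstream of the site A was most frequent at 18 nt (50.2% of genes) and T at 8 nt (54.6%). The site itself was a T in 55.8% of genes and in none an A, and the next base was A in 97.6% of genes.

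**Figure D5:**
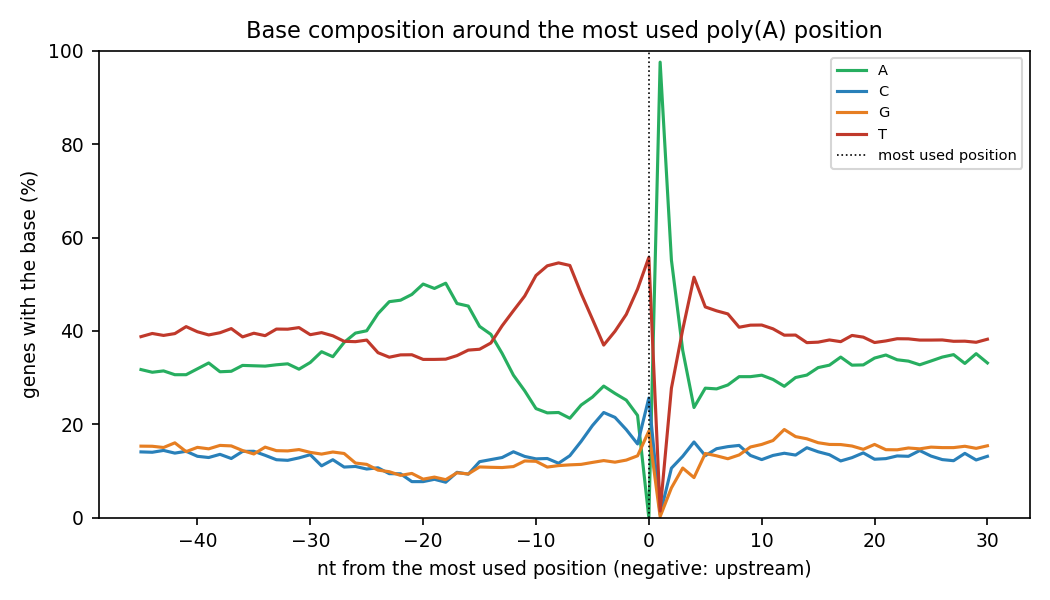
Share of genes (y axis, %) with each base at each distance in nt from the most used poly(A) position (x axis, negative upstream), over 3818 genes. Upstream of the site A is highest at 18 nt (50.2%) and T at 8 nt (54.6%); T makes up 55.8% at the site and A 97.6% directly after it.

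Fission yeast carries many ribosomal protein genes in duplicate. Some copies had nearly the same mean position: rpl2001 and rpl2002 at 64.4 ± 1.75 and 64.2 ± 0.0881 nt (SD, n = 2), rps801 and rps802 at 44.1 ± 0.0615 and 44.0 ± 2.92 nt, and rpl101 and rpl102 at 51.7 ± 0.0645 and 51.2 ± 0.116 nt. Their most used sites differed, at 45 and 64 nt for rpl2001 and rpl2002 and 44 and 32 nt for rps801 and rps802. Those of rpl101 and rpl102 lay at 54 and 24 nt. Other copies had mean positions far apart: rps1001 and rps1002 at 205 ± 9.67 and 35.6 ± 0.0862 nt, rpl3401 and rpl3402 at 82.0 ± 0.0430 and 224 ± 0.593 nt, and rpl1801 and rpl1802 at 181 ± 0.423 and 46.9 ± 0.316 nt. These far pairs differed by more than the spread between replicates. Over 62 pairs of 109 genes the median difference was 31.4 nt, against 26.1 nt for random pairings of the same genes, so copies were not found to be closer than other ribosomal protein genes (one-sided permutation p = 0.902).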

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

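The tests of read depth, window, gene copies, priming and end assignment were chosen only after results were seen. The design has a single group, so no biological explanation was tested.

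Reads inside the ORF are outside the comparisons of the report, and some genes had many. They made up at least 20% of the reads in both replicates, with at least 500 ORF reads in each, for 12 genes. Among them the share was 100% for SPBC27.05, 99.99% for SPBC29A3.21, 98.46% for SPAPB18E9.05c, 86.0% for mmp1, which encodes an endopeptidase subunit, 82.38% for set11, 78.28% for rsm27, which encodes a mitochondrial ribosomal protein, 77.3% for trm141, 74.92% for cho2, an enzyme of phospholipid synthesis, 73.67% for cyp9, 54.53% for mug161 and 47.12% for SPCC1235.01. Over all features ORF reads were 0.333% of ORF and window reads in replicate A (95% Wilson interval 0.331% to 0.334%) and 0.358% in B (0.357% to 0.360%). Transcripts of another annotated gene on the same strand may account for such reads, but only 2 of the 12 genes, SPBC29A3.21 and SPCC1235.01, overlap one (1.12% of other coding genes do; two-sided Fisher's exact p = 0.00802). For the other 10 the tables argue against an annotated overlapping gene, and priming inside the ORF, unannotated transcripts and sites within the ORF stay open. Window reads were also found at tRNA genes: 6 of them had at least 50 reads in both replicates.

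Genes of cytosolic ribosomal proteins ended close to the stop codon, and depth, the window and reads shared between gene copies were weighed as technical sources. Matched one to one with the non-ribosomal gene nearest in read total, within 0.5 on the log2 scale, 39 of them still lay closer (difference -58.6 nt, 95% bootstrap interval -79.5 to -43.7), which argues against depth as the whole cause, though this covers only the 39 and the gap was smaller than -92.9 nt over all genes. Among genes with an annotated end inside the window the difference was -80.6 nt (interval -87.7 to -74.0), so the 400 nt limit is unlikely to be the source. The 30 genes without another copy ended at a median of 55.5 nt, -92.3 nt from non-ribosomal genes (interval -103.4 to -83.7), which argues against shared reads as the source. A part played by depth stays open for the deepest genes, which have no counterpart of equal depth.

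Almost every most used site was followed by a genomic A. Priming at A stretches could place sites there, but 16.8% of the sites had at least 6 A in the next 10 nt, against 9.04% of random positions, which argues against it for most genes and leaves it open for these. No read was placed on an A, as it would be if ends inside a run of A were moved to the base before it. Random placement followed by that move gives 52.8% of sites followed by A, below the observed 97.6%, so the move alone does not give the pattern. A preference of cleavage for A and a filter in the authors' processing stay open.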

How the results depend on the processing

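The alternatives on annotated ends, ribosomal protein genes, core histones, list members off their theme, reads past the next ORF and groups by distance were chosen only after results were seen. The share of sites with a signal (excess 26.5 to 35.8 points), the correlation with distance (rho 0.310 to 0.402) and the paralogue pairs (27 to 33 nt) kept their direction and side of the threshold under every alternative run. Without each replicate in turn 3 to 4 lists passed for position, 2 for width and 3 for similarity, the orientation difference was 27.04 to 30.63 nt and the median position 143 to 144.1 nt. The orientation difference was 0.737 nt with a next gene of any kind and -14.9 nt within groups by distance. Position lists passing were 2 with median positions, 1 with the next gene over 400 nt away, where 19 lists could be tested, 6 with means over members and 5 without a read filter. Cytosolic ribosomal protein genes passed for position under all 16 alternatives that tested them (differences -136 to -44.0 nt); the spliceosome lost its call under 4 of 17, septation genes under 4 of 16 and kinases under 1 of 17. For width 0 lists passed against depth-matched random lists, 1 with the next gene over 400 nt away, 4 with the standard deviation and 1 without ribosomal protein genes, a list fewer by construction. For similarity 1 passed with positions 1 to 300, 1 with the next gene over 400 nt away and 1 with annotated ends within 400 nt, and with profiles shifted to a common mean 2 lists lost their call and 2 others gained it. The cell wall list turned to -1.54 with the effective number of sites as width and passed (adjusted permutation p = 0.0427), and the ligases to -0.484 points with profiles shifted to a common mean. The median position was 141.8 nt from median positions, 141 nt from most used positions, 153.7 nt without a filter, 139.8 nt at 200 reads, 130.2 nt for positions 1 to 300, 142.6 nt without sites under 5% and 147.8 nt without ribosomal protein genes. The median replicate difference was 0 nt for median and most used positions, 6.97 nt without a filter, 3.83 nt at 200 reads and 4.94 nt for positions 1 to 300. Except where stated, the cause was not tested.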

Other observations

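All tests below were chosen only after results were seen. Core histone genes ended far from the stop codon. Of 8 measured, 7 ended at 282 nt or beyond: hta1 (363 ± 0.576 nt, SD, n = 2), the histone variant gene pht1 (342 ± 1.06 nt), hht3 (325 ± 8.47 nt), hht1 (310 ± 0.877 nt), hhf3 (289 ± 0.155 nt), hhf2 (283 ± 3.63 nt) and hhf1 (282 ± 6.75 nt), while hht2 ended at 148 ± 0.333 nt. The median of these genes lay 156 nt above that of other genes (adjusted permutation p = 0.00745), where the list as fixed, mostly histone chaperones and modifiers, lay 37.3 nt above (adjusted permutation p = 0.4).

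The exact canonical signal was more frequent in ribosomal protein genes. AATAAA lay upstream of the most used site in 51 of 139 of them (36.7%), against 19.95% of other genes (two-sided Fisher's exact p = 0.000225 adjusted over the 27 lists). No other list passed; the lowest adjusted p among them was 0.363 by the same exact test. With single-base variants included the share was 78.4% in ribosomal protein genes, 80.7% in ribosome biogenesis, 80.3% in mitochondrial ribosomal protein and 78.9% in spliceosome genes, and these shares were not tested against each other. The AATAAA comparison was not matched on read depth or position. Ribosomal protein genes are deeper (median read total 152949) and end closer to the stop codon (median 54.8 nt), and whether this affects the share was not tested.

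In some convergent genes the most used site lay past the stop codon of the gene that faces them. The most used site of sil1 lay 332 nt past the stop codon of its neighbour, that of tam8 326 nt and that of sdj1 319 nt. These 3 had the largest such distances among 134 genes. Their mean positions were 169, 353 and 315 nt. The most used site of sil1 held 22.6% of its reads, and tam8 had 85 reads in A and 112 in B. Whether such reads belong to the gene or to another transcript was not tested.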
